A study of Mus musculus with 6 samples.

How the data were processed

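Liver RNA from C57Bl6/J mice, newborn according to the labels, was measured on 6 Affymetrix arrays, 2 for each of 3 maternal diets. Per the labels' protocols, each array carried biotin-labelled total RNA from a pool of 3 livers, and each diet had duplicate pools. The groups were taken from the sample titles as Control, ALA (alpha-linolenic acid) and SFA (saturated fatty acids), with replicates 1 and 2 in each. The labels give no litter, sex or time of collection for the pools.

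The deposited values are on the log2 scale, as their range from 1.98 to 13.1 shows, although the log base is not written with them. They were made with RMA (robust multi-array average) and Partek 6.6, per the submitters' processing notes. The background and probe summary settings and the annotation version are not stated there. No further scaling was applied before the tests.

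The table held 35556 probes. Gene symbols came from the platform annotation, and their current names were checked by Entrez identifier against the RefSeq annotation of the mouse assembly GRCm38.p6. Of the 21789 probes with 1 symbol, 21698 were found there and 0 symbols changed. The 1621 probes annotated to several genes and the 12146 with no listed gene were left out of the gene tests. A gene with several probes was represented by the probe with the highest mean, which left 19938 genes. The 10977 genes whose mean log2 signal over the 6 arrays was at least 5 were tested.

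Tests were run in R 4.3.3 with limma 3.58.1. A linear model with a mean for each diet was fitted to all 6 arrays, which leaves 3 residual degrees of freedom per gene, and moderated by empirical Bayes with default settings. The contrasts were ALA minus control, SFA minus control and ALA minus SFA, beside a moderated F test of any difference between the 3 diets. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and genes with an adjusted p below 0.05 were called changed. The p-values of the gene and list tests are two-sided. Those of the gene tests measure only the spread between these samples, which may be technical, since the labels do not say whether the duplicate pools came from different animals. Camera also sets a list against the spread between genes. The permutation tests of the closing section shuffle genes and not arrays, so their p-values measure the spread between genes. The cell type test and the chances given for the pools are one-sided. Errors are standard errors (SE) from the same fit with n = 2 arrays per group.

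Gene lists for metabolic pathways, growth, stress and the cell types that a dissected newborn liver could hold were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. The 31 lists with at least 5 measured genes were tested with limma's camera at its preset correlation of 0.01 between genes, and adjusted over the lists. Camera asks whether a list moved relative to the other genes. For each list the number of called members is given both over all genes and adjusted over the list alone. Camera was repeated with a correlation estimated from the data, and fry, which tests whether a list moves 1 way on balance, was run on the same lists. Further lists, used only in the closing section, were written after the data were examined.

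Named genes are, for each contrast and direction, the 10 called genes with the largest change whose arrays did not overlap between the groups. Gene models without a common name and pseudogenes were skipped. A direction with fewer than 8 such genes was to be filled up to 8 from those with the smallest p and a log2 change of at least 0.58. The 4 members with the largest change are added for each list that passed or had a called member, and 22 genes of lipid, glucose and growth metabolism were fixed for reporting in each contrast. Of the 22, 18 have values, 1 was below the signal minimum, and 3 are not reported here. Other genes named in the text are said to have been chosen after their values were seen.

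Because both diets were compared with the same 2 control arrays, the overlap and correlation of their effects were set beside 100 simulated sets with no diet effect and the fitted spread of each gene. The controls were too few to be split between the comparisons.

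The procedure was tested on simulated data with the fitted spread, 10977 genes and 200 changed genes in each of 5 sets, in the comparison of ALA with control. It recovered 22.5% of genes changed by 0.58 on the log2 scale, 90.3% of those changed by 1 and 98.8% of those changed by 2. On average 14.2 unchanged genes were called in that comparison and 0.2 in the comparison of SFA with control, where nothing had been changed. The 14.2 is a larger share of the calls than the 0.05 at which the adjusted threshold aims, even if all 200 changed genes were called. At an unadjusted p below 0.05, camera called 20 of 20 simulated lists shifted by 0.5 and 0 of 20 unshifted lists. The genes were simulated independently of each other, so these runs do not test the preset correlation.

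Alternatives covered the signal minimum, the choice of probe, 3 rescalings (75th percentile centring, cyclic loess and quantile normalization), the moderation of the spread, a replicate block, the threshold, the arrays entering the fit, the list test, and leaving out each array in turn. The number of arrays limits the precision of every value.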

Results

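Gene expression was compared in whole livers of mice, newborn according to the labels, whose mothers had eaten 1 of 3 isocaloric diets. Each diet held 6 g% of oil. Whether the control livers were of that age is questioned in the closing section. The control diet held soybean oil, the ALA diet flaxseed oil, which is rich in the omega-3 fatty acid alpha-linolenic acid, and the SFA diet coconut oil, which is rich in saturated fatty acids. The labels give 31.6% for alpha-linolenic acid in the ALA diet and 48.51% for saturated fatty acids in the SFA diet. Each diet had 2 arrays, each from a pool of 3 livers taken within 1 day of birth according to the labels. Over 35556 probes, the median log2 signal was 4.76 and 4.82 on the SFA arrays and between 4.90 and 4.96 on the other arrays. The highest signal was 12.76 and 12.67 on the SFA arrays and between 13.07 and 13.12 on the others. Across the 10977 tested genes, duplicate arrays correlated with r = 0.977 for control, 0.978 for ALA and 0.986 for SFA, and arrays of different diets with r from 0.927 to 0.964. Genes are not independent replicates in these correlations.

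The sex-linked genes differed between the pools. Xist, the RNA that silences 1 X chromosome in female cells, had a log2 signal of 3.76 and 4.24 on the ALA arrays, 9.46 and 9.51 on the SFA arrays, and 10.7 and 8.34 on the control arrays. Eif2s3y, a Y-linked translation factor gene, was at 7.74 and 7.80 on the ALA arrays, 4.11 and 3.79 on the SFA arrays, and 3.63 and 7.95 on the control arrays. The Y-linked genes Uty and Kdm5d followed Eif2s3y, and with 4 measured genes the sex-linked list was too short to be tested as a list. The ALA arrays thus had the signal of male pools, the SFA arrays and control replicate 1 that of female pools, and control replicate 2 that of a mixed pool. Every contrast between the diets is also a contrast between pools of different sex makeup.

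**Figure D1:**
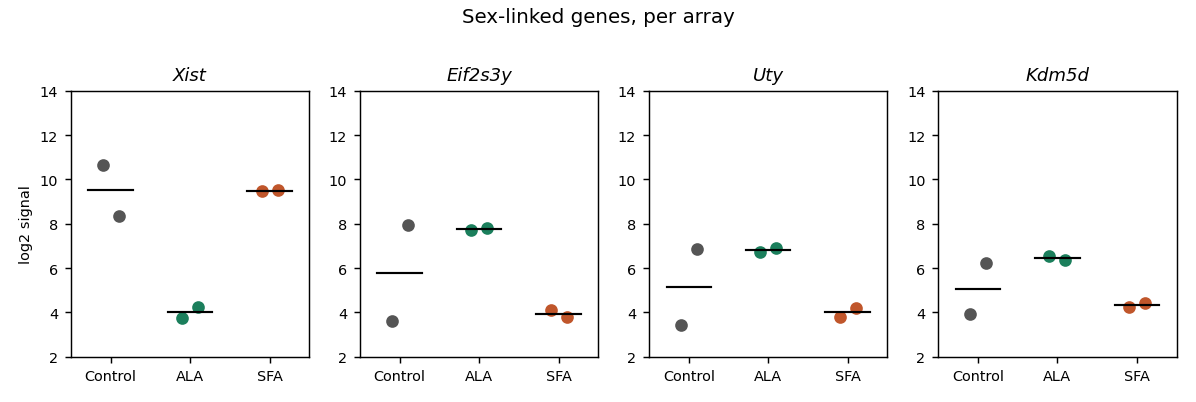
Log2 signal (y axis) of the X-linked gene Xist and the Y-linked genes Eif2s3y, Uty and Kdm5d on each array, by maternal diet (x axis). Points are the 2 arrays of a group and lines their mean; Xist was at 3.76 and 4.24 on the ALA arrays against 9.46 and 9.51 on the SFA arrays.

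The overall question of the series is whether maternal diet changes liver expression in the offspring. The moderated F test called 1477 of 10977 genes (13.5%), with 3798 at an unadjusted p below 0.05. Without control replicate 1 the number was 643, without control replicate 2 it was 318, without ALA replicate 2 it was 880, without SFA replicate 1 it was 364, and without SFA replicate 2 it was 347.

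Against control livers, Hamp (probe 10562169), which encodes the iron hormone hepcidin, fell by 6.57 on the log2 scale in livers of ALA offspring (SE 0.44, adjusted p = 0.0024, n = 2 arrays per group), and its paralog Hamp2 fell by 3.17 (SE 0.24). Cyp7b1, which encodes an enzyme of the alternative bile acid pathway, fell by 4.18 (SE 0.72). The carboxylesterase gene Ces1f fell by 3.57 (SE 0.26), and Hspb1, a small heat shock protein gene, fell by 2.75 (SE 0.18). The fetal cytochrome P450 gene Cyp3a16 rose by 3.80 (SE 0.41). Lpl, the lipoprotein lipase gene, which in mouse liver is known for its expression around birth, rose by 3.45 (SE 0.30), and the growth regulator gene Gpc3 by 3.33 (SE 0.41). In all, 871 of 10977 genes were called (7.94%), 561 higher and 310 lower on ALA.

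Among the other called genes with the largest changes, Dmbt1, which encodes a mucosal scavenger-receptor protein, rose by 3.75 (SE 0.37). The metallothionein gene Mt2 rose by 2.77 (SE 0.39), and Lcn2, which encodes an acute phase protein that withholds iron from bacteria, by 2.76 (SE 0.64). Cyp2c38, a member of the cytochrome P450 2C family, fell by 4.80 (SE 0.75), and the NADPH oxidase gene Nox4 fell by 3.49 (SE 0.60). Xist, which follows the sex of the pools, fell by 5.50 (SE 0.65). The control mean of Cyp3a16, Gpc3 and Dmbt1 and the ALA mean of Nox4 and Xist were no higher than 4.42. That is the highest signal of a Y-linked gene on an array without Y-linked signal. A group mean this low may be background, so the sizes of these changes are uncertain beyond their SE. Over all tested genes, both ALA arrays lay on the same side of both control arrays for 55.0%, where 4 independently varying arrays would give 33.3%. Duplicates from the same animals, or another difference between the pools, can raise that share without a diet effect.

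**Figure D2:**
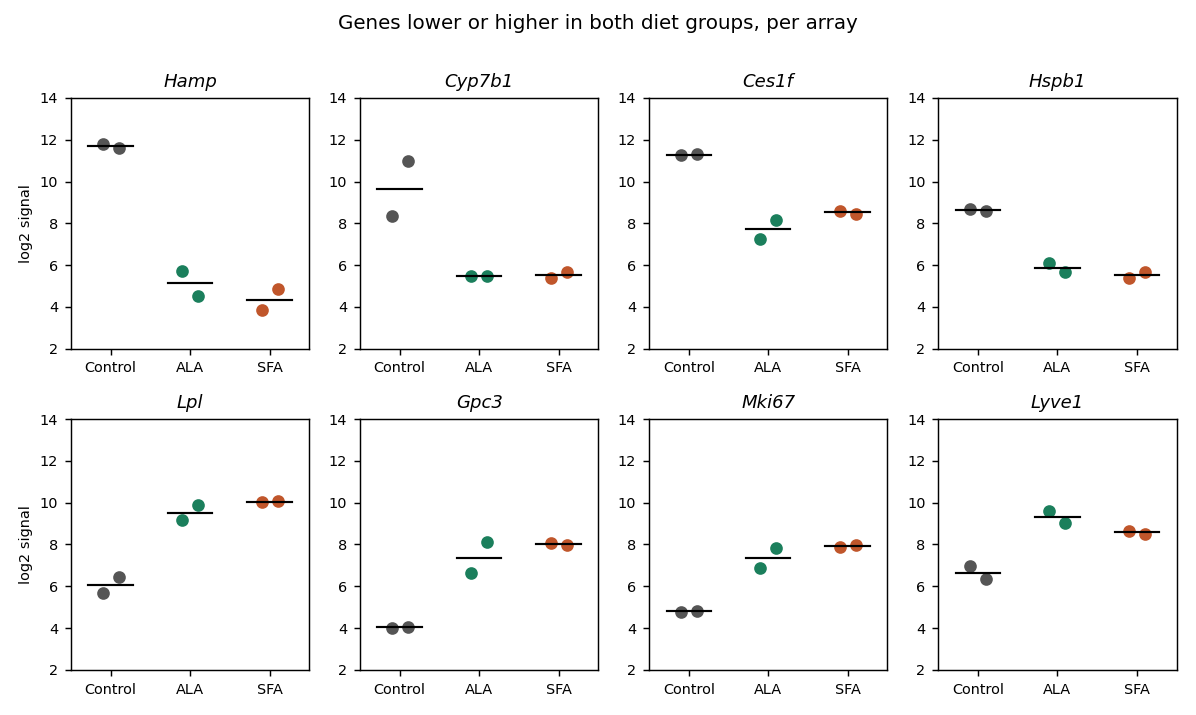
Log2 signal (y axis) of 8 genes on each array, by maternal diet (x axis); points are the 2 arrays of a group and lines their mean. Hamp was at 11.8 and 11.6 on the control arrays and between 3.83 and 5.73 on the other 4, while Gpc3 was at 4.03 and 4.07 on the control arrays and between 6.64 and 8.11 on the others.

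Genes of dividing cells, macrophages, endothelium, stellate cells and megakaryocytes rose on ALA, while the lists of erythroid cells, granulocytes, lymphoid cells and bile duct cells were not called (camera adjusted p = 0.226, 0.816, 0.988 and 0.251). Of 28 cell cycle genes 13 rose and 0 fell over all genes (18 and 0 adjusted over the list alone, median 0.99, camera adjusted p = 5.24e-11, adjusted p = 0.515 with an estimated correlation). The cyclin gene Ccna2 rose by 2.73 and the proliferation marker gene Mki67 by 2.54. Of 18 macrophage and Kupffer cell genes 15 rose and 0 fell (16 and 0 adjusted over the list alone, median 0.91, camera adjusted p = 1.07e-11, adjusted p = 0.448 with an estimated correlation). The complement genes C1qb and C1qc rose by 1.79 and 1.67, and the Kupffer cell receptor gene Vsig4 by 1.65. Of 20 endothelial genes 11 rose and 0 fell (17 and 0 adjusted over the list alone, median 0.98, camera adjusted p = 5.73e-12, adjusted p = 0.515 with an estimated correlation). Lyve1, a hyaluronan receptor gene of sinusoidal endothelium, rose by 2.67. Of 20 genes of stellate cells, fibroblasts and mesothelium 11 rose and 0 fell (18 and 0 adjusted over the list alone, median 0.87, camera adjusted p = 5.73e-12, adjusted p = 0.438 with an estimated correlation). The matrix genes Postn and Col3a1 rose by 2.25 and 1.22. Of 11 megakaryocyte and platelet genes 5 rose and 0 fell (6 and 0 adjusted over the list alone, median 0.73, camera adjusted p = 3.61e-05, adjusted p = 0.438 with an estimated correlation). The integrin gene Itgb3 rose by 1.70 and the platelet chemokine gene Pf4 by 1.22.

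Genes of the fetal liver moved with them. Of 15 fetal and growth-associated imprinted genes 5 rose and 0 fell (11 and 0 adjusted over the list alone, median 0.74, camera adjusted p = 1.64e-05, adjusted p = 0.426 with an estimated correlation). They were Gpc3, Plagl1, the RNA-binding protein gene Igf2bp3 at 2.46, and the imprinted genes Grb10 at 2.24 and Mest at 1.79. The control mean of Igf2bp3 was no higher than 4.42, so the size of its change is uncertain on both diets. Plagl1, an imprinted transcription factor gene, is named after its value was seen. The fetal serum protein gene Afp and the growth factor gene Igf2 did not pass, at 0.60 and 0.74. Without control replicate 1 the median of the list was 0.46. The erythroid list was not called, but 3 of its 16 measured genes rose. These were the red cell anion exchanger gene Slc4a1 at 2.22, the transferrin receptor gene Tfrc at 2.17 and the carbonic anhydrase gene Car2 at 1.77. Of 25 genes of mature hepatocyte functions 1 rose, the urea cycle gene Asl, and 0 fell, and albumin (Alb) was at -0.06.

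Cholesterol synthesis genes were lower on ALA as a group. All 20 measured genes had a negative log2 change with a median of -0.89, and 2 fell over all genes (5 adjusted over the list alone, camera adjusted p = 1.43e-06, adjusted p = 0.547 with an estimated correlation). These 2, named after their values were seen, were the mevalonate pathway kinase gene Pmvk, at -1.04 (SE 0.21), and the sterol desaturase gene Sc5d, at -0.66 (SE 0.15). The largest changes did not pass at the spread between the arrays. Cyp51, a sterol demethylase gene, was at -1.89 (SE 0.66), the isomerase gene Idi1 at -1.74 (SE 0.50) and the squalene epoxidase gene Sqle at -1.77 (SE 0.75). Sqle had a log2 signal of 4.99 and 7.59 on the ALA arrays and of 7.60 and 8.51 on the control arrays. Without ALA replicate 1 the list was still called (adjusted p = 0.00455) but its median was -0.29, and without ALA replicate 2 it was -1.38.

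**Figure D3:**
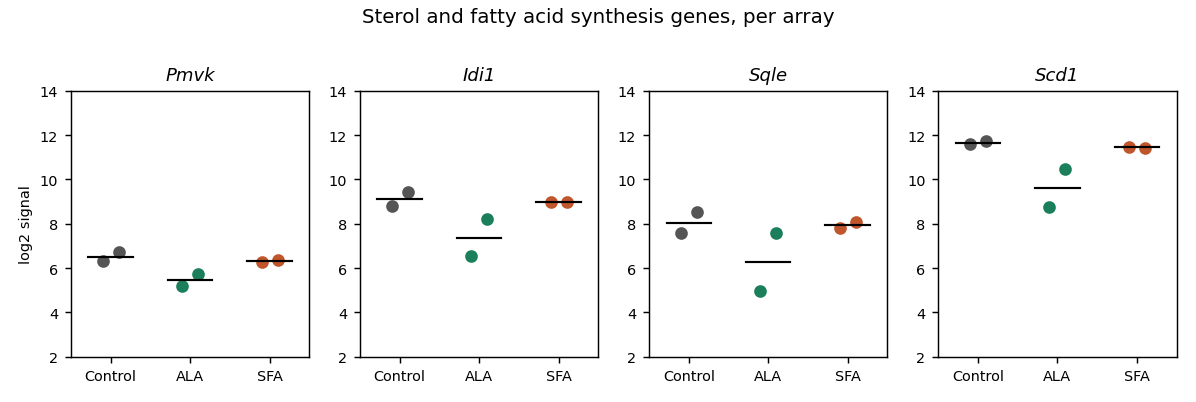
Log2 signal (y axis) of the cholesterol synthesis genes Pmvk, Idi1 and Sqle and the fatty acid desaturase gene Scd1 on each array, by maternal diet (x axis); points are the 2 arrays of a group and lines their mean. Sqle was at 4.99 and 7.59 on the ALA arrays, 7.60 and 8.51 on the control arrays and 7.80 and 8.09 on the SFA arrays.

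Fatty acid synthesis genes were lower on balance. Of 25 genes 3 rose and 5 fell (3 and 11 adjusted over the list alone, median -0.45, camera adjusted p = 0.0252, adjusted p = 0.547 with an estimated correlation). The stearoyl-CoA desaturase gene Scd1 fell by 2.04 (SE 0.47), and the malic enzyme gene Me1 fell by 1.71 (SE 0.21). Srebf1, a transcription factor gene of lipogenesis, fell by 0.77 (SE 0.17), while the lipogenesis regulator gene Thrsp rose by 1.78 (SE 0.21). The fatty acid synthase gene Fasn (-0.82), the elongase gene Elovl6 (-0.79) and the desaturase genes Fads1 (-0.32) and Fads2 (-0.20), whose enzymes act in the conversion of dietary alpha-linolenic acid, did not pass. Without ALA replicate 1 the list was no longer called (median -0.28, adjusted p = 0.199).

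Smaller groups also moved on ALA. Of 31 proteasome genes 0 rose and 2 fell (0 and 6 adjusted over the list alone, median -0.38, camera adjusted p = 1.69e-07, adjusted p = 0.246 with an estimated correlation). The 2 were the core subunit genes Psma1, at -0.71, and Psma3, at -0.51. Of 18 gluconeogenesis and glycogen genes 5 rose and 0 fell (7 and 1 adjusted over the list alone, median 0.33, camera adjusted p = 0.00859, adjusted p = 0.563 with an estimated correlation). The coactivator gene Ppargc1a rose by 1.63 and the glucose-6-phosphate transporter gene Slc37a4 by 1.05, whereas the rate-limiting enzyme gene Pck1 was at 0.31 and did not pass. Of 29 acute phase genes 5 rose and 2 fell (9 and 2 adjusted over the list alone, median 0.26, camera adjusted p = 0.0161, adjusted p = 0.817 with an estimated correlation). The 2 that fell were Hamp and Hamp2. Of 18 clock genes 8 rose and 1 fell (8 and 2 adjusted over the list alone, median 0.30, camera adjusted p = 0.0477, adjusted p = 0.515 with an estimated correlation). Usp2, a clock-driven protease gene, was at 1.75, the repressor gene Ciart at 1.45 and the nuclear receptor gene Nr1d1 at -1.31. Of 22 oxidative stress and glutathione genes 3 rose and 3 fell (3 and 6 adjusted over the list alone, median -0.21, camera adjusted p = 0.0477, adjusted p = 0.515 with an estimated correlation). Its members went both ways: the glutathione synthesis gene Gclc fell by 1.26, and the heme oxygenase gene Hmox1 rose by 1.18. The gluconeogenesis call was lost without control replicate 2 (median 0.14, adjusted p = 0.141), and the acute phase call without ALA replicate 1 (median 0.05, adjusted p = 0.333) or control replicate 1 (median -0.01, adjusted p = 0.330). The gluconeogenesis median was 0.58 without control replicate 1, and the acute phase median was 0.51 without control replicate 2 and 0.45 without ALA replicate 2. The clock call was lost without control replicate 1 (adjusted p = 0.136), ALA replicate 2 (median 0.17, adjusted p = 0.0988) or either SFA array (0.0529), and the oxidative stress call without control replicate 1 (0.0894), control replicate 2 (0.0698), ALA replicate 1 (0.119) or either SFA array (0.0615).

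The other 18 of the 31 lists were not called on ALA (adjusted p from 0.0986 to 0.988), among them fatty acid oxidation and bile acid synthesis. The nuclear receptor gene Ppara was at -0.0029, the carnitine palmitoyltransferase gene Cpt1a at 0.20, and Cyp7a1, the rate-limiting enzyme gene of bile acid synthesis, at 0.33. Of the other genes fixed for reporting, Cyp4a14 was at 0.29, Igf1 at 0.07, Igfbp1 at 1.66, the fatty acid transporter gene Cd36 at -0.93 and the sterol exporter gene Abca1 at 0.14, and none of these passed. The number of called genes was 475 without control replicate 1, 267 without control replicate 2, 453 without ALA replicate 1, 384 without ALA replicate 2 and 448 without either SFA array, and 2714 genes had an unadjusted p below 0.05.

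SFA offspring differed from control in many of the genes that ALA offspring did, and in the same direction. Hamp fell by 7.35 on the log2 scale (SE 0.44, adjusted p = 0.000774, n = 2 arrays per group). Hamp2 was at -4.23 (SE 0.24), Cyp7b1 at -4.13 (SE 0.72) and Hspb1 at -3.10 (SE 0.18). Cyp3a16 rose by 5.15 (SE 0.41), Lpl by 3.98 (SE 0.30) and Gpc3 by 3.96 (SE 0.41). Akr1c18, which encodes a progesterone-reducing enzyme, rose by 4.76 (SE 0.45). The SFA mean of Hamp and Hamp2 and the control mean of Cyp3a16, Gpc3 and Akr1c18 were no higher than the 4.42 given above. The sizes of these changes are thus uncertain beyond their SE. In all, 1512 of 10977 genes were called (13.8%), 727 higher and 785 lower on SFA, a balance that turned after 75th percentile centring (745 and 743), cyclic loess (854 and 664) and quantile normalization (741 and 672). The groups did not overlap for 64.2% of the tested genes, where independently varying arrays would give 33.3%, with the limit given for ALA.

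Among the genes that fell were the natriuretic peptide receptor gene Npr2 at -3.47 (SE 0.23), the carboxylesterase gene Ces3b at -3.51 (SE 0.71) and Mup3, which encodes a major urinary protein, at -3.24 (SE 0.46). The xenobiotic receptor gene Nr1i3 fell by 1.36 (SE 0.12), and the aldehyde oxidase gene Aox1 fell by 1.93 (SE 0.17). Xist was at -0.02 against control, with control replicate 2 carrying Y-linked signal and both SFA arrays not.

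Cell cycle genes had the largest median change of the 31 lists on SFA. Of 28 cell cycle genes 22 rose and 0 fell (26 and 0 adjusted over the list alone, median 1.63, camera adjusted p = 5.18e-18, adjusted p = 0.666 with an estimated correlation). Ccna2 was up by 3.93, the mitotic kinase gene Cdk1 by 3.24 and the mitotic cyclin gene Ccnb2 by 3.01. Of 20 genes of stellate cells, fibroblasts and mesothelium 16 rose and 0 fell (17 and 0 adjusted over the list alone, median 1.00, camera adjusted p = 5.80e-12, adjusted p = 0.587 with an estimated correlation). Postn rose by 2.17 and the smooth muscle actin gene Acta2 by 2.03. Of 18 macrophage and Kupffer cell genes 11 rose and 0 fell (13 and 0 adjusted over the list alone, median 0.84, camera adjusted p = 7.37e-09, adjusted p = 0.666 with an estimated correlation). Vsig4 rose by 1.52. Of 20 endothelial genes 10 rose and 0 fell (13 and 0 adjusted over the list alone, median 0.73, camera adjusted p = 1.81e-06, adjusted p = 0.732 with an estimated correlation). Lyve1 rose by 1.94. Of 11 megakaryocyte and platelet genes 6 rose and 0 fell (7 and 0 adjusted over the list alone, median 0.80, camera adjusted p = 7.03e-06, adjusted p = 0.587 with an estimated correlation). The platelet genes Ppbp and Pf4 rose by 3.00 and 2.35. Of 15 fetal and imprinted genes 7 rose and 0 fell (8 and 1 adjusted over the list alone, median 0.78, camera adjusted p = 1.81e-06, adjusted p = 0.587 with an estimated correlation). Igf2bp3 rose by 2.77, Mest by 2.03, Afp by 1.68 and Igf2 by 1.56. Without control replicate 2 the median of the fetal list was 0.47 and that of the endothelial list 0.46. The 38 respiratory chain genes were called as higher by a small margin (1 rose and 1 fell, 1 and 0 adjusted over the list alone, median 0.15, camera adjusted p = 0.00858, adjusted p = 0.727 with an estimated correlation). The members that moved were the complex I gene Ndufs4, up by 0.72, and Ndufa4, which fell by 0.63.

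Cholesterol synthesis was not called on SFA: 0 of 20 genes passed, the median was -0.08, the mean -0.03, and camera gave the direction as up with an adjusted p of 0.892. Of 25 fatty acid synthesis genes 1 rose and 3 fell (1 and 4 adjusted over the list alone), without a call for the list (adjusted p = 0.633). The SREBP anchor gene Insig2 was at 1.36 (SE 0.13), Srebf1 at -1.03, the carbohydrate response factor gene Mlxipl at -1.23 and Me1 at -1.21. Scd1 was at -0.21, Fasn at -0.41, Elovl6 at -0.39, Fads1 at 0.21 and Fads2 at -0.02, and none passed. The kinase gene Pdk4, which restrains glucose oxidation, rose by 1.95 (SE 0.45). Of 18 clock genes 2 rose and 7 fell (2 and 7 adjusted over the list alone) without a call for the list (adjusted p = 0.197). The core activator gene Arntl was at 1.99 and the repressor gene Cry1, named after its value was seen, at 1.07, while the output gene Dbp was at -2.18, Per3 at -1.19 and Per2 at -1.17.

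The other 24 lists were not called on SFA (adjusted p from 0.0759 to 0.892), and in the erythroid list 4 of 16 genes rose, among them Slc4a1 by 2.52 and Tfrc by 2.51, and 1 fell. Of the fixed genes not yet given, Cyp7a1 was at -0.54, Ppara at -0.29, Cpt1a at 0.02, Cyp4a14 at 0.31, Pck1 at 0.01, Igf1 at -0.02, Igfbp1 at 1.38, Alb at -0.14, Cd36 at -0.70 and Abca1 at -0.21, and none of these passed. The number of called genes was 735 without control replicate 1, 367 without control replicate 2, 245 without SFA replicate 1 and 362 without SFA replicate 2. The comparison without control replicate 2 sets pools with female signal against each other.

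**Figure D4:**
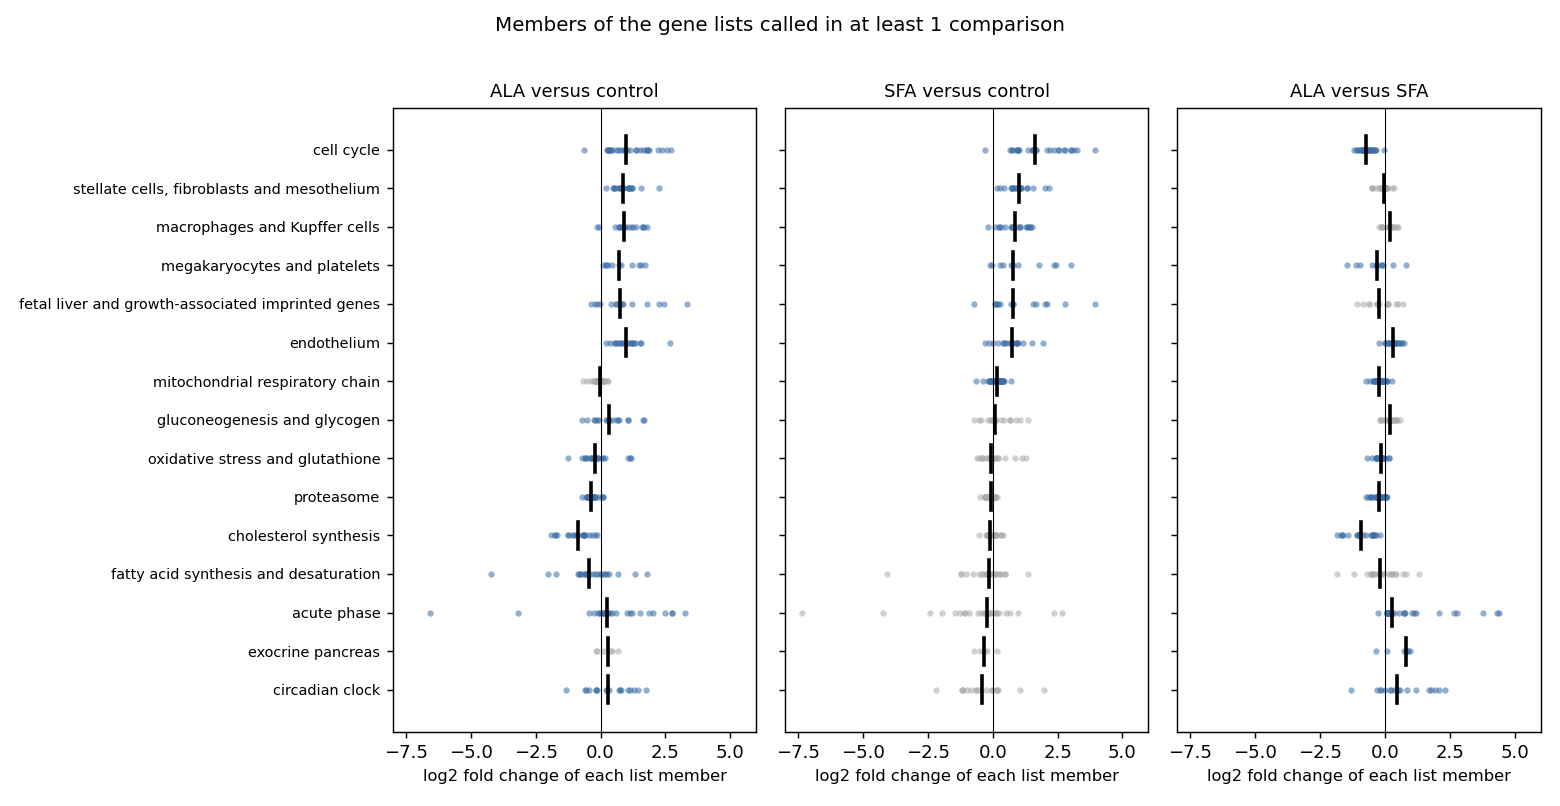
Log2 fold change (x axis) of each member of the gene lists (y axis) called in at least 1 comparison, in 3 panels for ALA versus control, SFA versus control and ALA versus SFA. Points are genes, blue where camera called the list in that comparison and grey where it did not, and the black bar is the list median, which for cell cycle genes was 0.99, 1.63 and -0.72.

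The changes on both diets were compared with each other. Of the genes called against control, 549 were called on both diets in the same direction, 373 higher and 176 lower, and 5 in opposite directions. Simulated sets with the shared controls and no diet effect gave 0.04 and 0.03 such genes on average, and independent lists of these sizes would share 37.2 and 22.2. Sets without any effect leave few genes to call, so they cannot show how much overlap the shared controls add among the called genes. Their spread is that between duplicate arrays, which may be technical. The log2 changes correlated across genes with r = 0.733 (Spearman 0.603), against 0.501 in the simulated sets, and their covariance was 0.177 against 0.0163, while the share of genes with the same sign was 70.7% against 66.7%. Part of this excess may come from the shared controls, since a control pool that differs from the others for its own reasons moves both comparisons alike. The 5 genes with opposite directions were Per2, Per3, the glutamate receptor gene Grik5, Klhl6 and the gene model Gm10590, all higher on ALA and lower on SFA, and the last 3 are named after their values were seen. Of the 317 genes called on ALA alone 35 also passed the direct test of ALA against SFA, and of the 958 called on SFA alone 91 did.

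Set directly against SFA, the called genes of ALA livers included genes of the clock. The period genes Per3 and Per2, which repress the clock's activators, were higher on ALA by 2.33 (SE 0.26) and 1.94 (SE 0.16) on the log2 scale with n = 2 arrays per group (adjusted p = 0.035 and 0.029). Ciart was higher by 2.09 (SE 0.33), Usp2 by 1.79 (SE 0.24) and Dbp by 1.72 (SE 0.20), whereas the activator gene Arntl was lower, at -1.29 (SE 0.15). The acute phase gene Orm3 was higher by 2.77 (SE 0.42) and Dmbt1 by 2.15 (SE 0.37). Akr1c18 was lower on ALA, at -2.67 (SE 0.45). It is among 26 measured genes known for higher expression in adult female liver, and the ALA pools had male signal and the SFA pools female signal. Those 26 genes had a median of -0.02 in this comparison. Akr1c18 was at 4.22 on control replicate 1, which also had female signal. Also lower on ALA were the water channel gene Aqp8 at -1.67 (SE 0.20) and the neutrophil granule gene Ngp at -1.27 (SE 0.17). With the sex of the pools, Xist was at -5.49 (SE 0.65), a size uncertain as above. In all, 168 of 10977 genes were called (1.53%), 120 higher and 48 lower on ALA, with 2463 at an unadjusted p below 0.05.

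**Figure D5:**
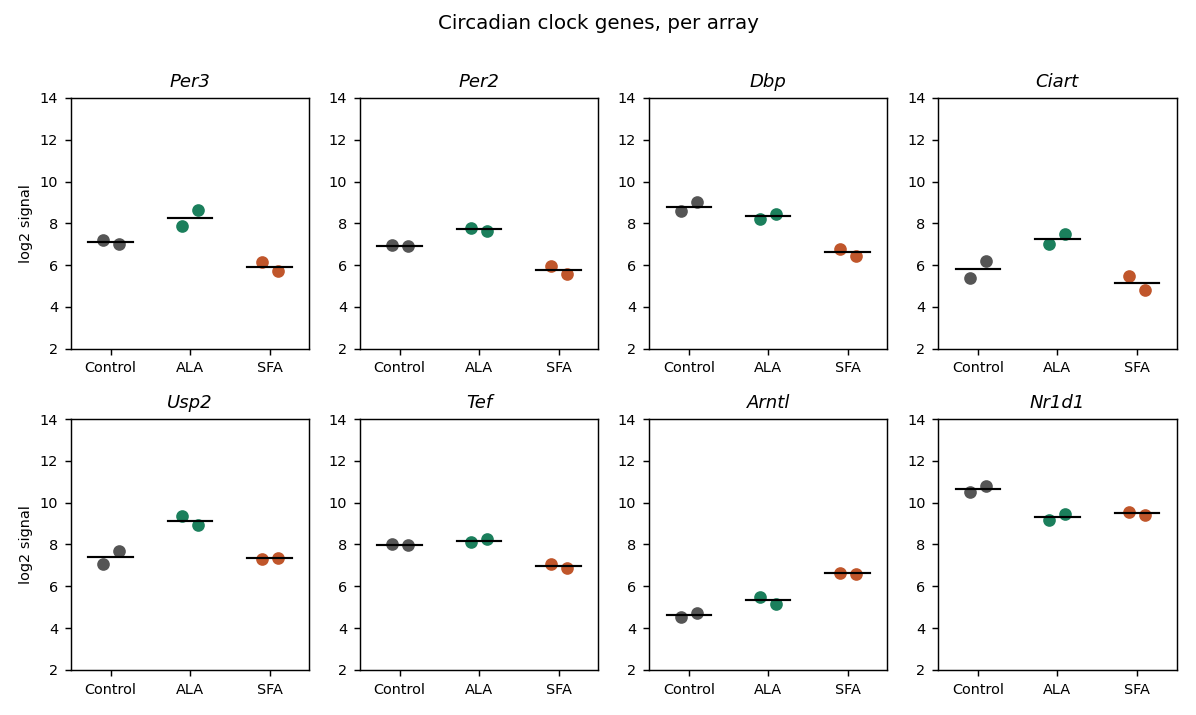
Log2 signal (y axis) of 8 circadian clock genes on each array, by maternal diet (x axis); points are the 2 arrays of a group and lines their mean. Per3 was at 7.88 and 8.64 on the ALA arrays, 6.13 and 5.72 on the SFA arrays and 7.21 and 7.03 on the control arrays, while Arntl was at 5.48 and 5.16 on ALA, 6.64 and 6.59 on SFA and 4.53 and 4.72 on control.

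Of 18 clock genes 6 were higher on ALA than on SFA and 1 was lower (10 and 1 adjusted over the list alone, median 0.48, camera adjusted p = 0.000317, adjusted p = 0.617 with an estimated correlation). Of 29 acute phase genes 1 was called higher (10 adjusted over the list alone, median 0.28, camera adjusted p = 2.29e-05, adjusted p = 0.715 with an estimated correlation; median 0.18 without ALA replicate 1). Its largest changes lay in genes that did not pass, the orosomucoid gene Orm2 at 4.42 (SE 0.80) and the serum amyloid genes Saa1 at 4.31 (SE 0.90) and Saa2 at 3.79 (SE 1.00). The size of the Saa1 change is uncertain, since its SFA mean was under 4.42. Its log2 signal was 8.95 and 6.63 on the ALA arrays, 2.94 and 4.00 on the SFA arrays and 3.43 and 5.61 on the control arrays. Of 20 endothelial genes 0 passed, with a median of 0.34 (0 adjusted over the list alone, camera adjusted p = 0.00851, adjusted p = 0.784 with an estimated correlation). Of 6 exocrine pancreas genes 2 were higher on ALA (4 adjusted over the list alone, median 0.80, camera adjusted p = 0.0365, adjusted p = 0.628 with an estimated correlation), the elastase gene Cela2a by 0.99 and the zymogen granule gene Sycn by 0.85.

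All 20 cholesterol synthesis genes had a lower mean on ALA than on SFA, with a median of -0.91 and 0 past the threshold (0 adjusted over the list alone, camera adjusted p = 6.31e-08, adjusted p = 0.628 with an estimated correlation). The median was -0.29 without ALA replicate 1. All 28 cell cycle genes were lower too, with a median of -0.72 and 0 past the threshold (7 adjusted over the list alone, camera adjusted p = 3.84e-09, adjusted p = 0.628 with an estimated correlation). Their median was -0.25 without ALA replicate 1 and -1.12 without ALA replicate 2. Proteasome genes had a median of -0.24 (0 of 31 passed, 2 adjusted over the list alone, camera adjusted p = 1.31e-05, adjusted p = 0.362 with an estimated correlation). Respiratory chain genes had a median of -0.21 (0 of 38 passed, 1 adjusted over the list alone, camera adjusted p = 1.51e-05, adjusted p = 0.617 with an estimated correlation). Oxidative stress genes had a median of -0.14 (0 of 22 passed, 2 adjusted over the list alone, camera adjusted p = 0.00480, adjusted p = 0.617 with an estimated correlation). Of 11 megakaryocyte and platelet genes Pf4 alone passed, at -1.12. The list was lower (1 higher and 3 lower adjusted over the list alone, median -0.31, camera adjusted p = 0.0340, adjusted p = 0.628 with an estimated correlation). The megakaryocyte call was lost without ALA replicate 2 (median -0.16, adjusted p = 0.0755) or SFA replicate 1 (0.101), and the pancreas call without ALA replicate 2 (median 0.42, adjusted p = 0.150) or SFA replicate 1 (0.0645).

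Among metabolic genes, Thrsp was higher on ALA than on SFA by 1.32 (SE 0.21), Apoa5 by 0.86 (SE 0.13) and Nr1i3 by 1.15 (SE 0.12), and the acetyl-CoA synthetase gene Acss2 was lower, at -1.18 (SE 0.14). Scd1 was at -1.82 (SE 0.47), Cyp7a1 at 0.87 (SE 0.20), Afp at -1.08 (SE 0.23) and Igf2 at -0.82 (SE 0.22), and none of these 4 passed. The same holds for Fasn at -0.41, Fads1 at -0.53, Fads2 at -0.19, Elovl6 at -0.40, Srebf1 at 0.26, Ppara at 0.28, Cpt1a at 0.18, Cyp4a14 at -0.03, Pck1 at 0.30, Igf1 at 0.09, Igfbp1 at 0.29, Alb at 0.08, Cd36 at -0.24 and Abca1 at 0.35. The other 21 lists were not called (adjusted p from 0.187 to 0.836).

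The gene count of this comparison rested on all 6 arrays. It was 11 without either control array, 36 without ALA replicate 2 (9 higher and 27 lower on ALA), and 0 by limma without ALA replicate 1, SFA replicate 1 or SFA replicate 2, where 2323, 1707 and 1634 genes had an unadjusted p below 0.05. The groups did not overlap for 55.8% of the tested genes, where independently varying arrays would give 33.3%, with the limit given for ALA against control.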

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

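The tests of the draw of pups, of liver maturity, of puberty, of the distance between ALA and SFA in the lists called on both diets, of the time of collection and of the place of control between the diets in the clock arms were chosen only after the results they measure had been seen, and the maturity test was narrowed to genes not named elsewhere after a run on all list members, and the distance test replaced one of opposite directions (0.903% of the genes called on both diets), which the shared control arrays made one-sided. The other tests were set down before.

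Probes with no listed gene, which the gene tests left out, also carried signal that differed between the diets. Of 4140 such probes above the signal minimum, 72 were called in ALA versus control (39 higher and 33 lower), or 1.74% against 3.23% of the other probes. In SFA versus control 641 were called (104 higher and 537 lower), or 15.5% against 10.2% of the other probes, and their median log2 change was -0.25 against -0.04. The SFA arrays also had lower medians over all probes (4.76 and 4.82) than the other arrays (4.90 to 4.96), and these probes were not tested after rescaling. In ALA versus SFA 211 were called (189 higher and 22 lower), or 5.10% against 1.44% of the other probes, and their median was 0.17 against 0.03.

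The sex-linked genes split the pools by diet: on the ALA arrays Xist was low and the Y-linked genes were high, and on the SFA arrays the reverse. With the widest gap in Xist and in the mean of 3 Y-linked genes as the border, 5 of 6 pools had the signal of a single sex, and if pups had been drawn at random for pools of 3 the chance of at least as many is 0.00464. The labels do not say whether duplicate pools hold different animals, and if the ALA duplicates and the SFA duplicates are each 1 set of animals, 3 of 4 sets had a single sex (chance 0.0508), so a random draw stays open. A border first set at a fixed distance below the highest signal counted all 6 pools (chance 0.000244) and was replaced after it was seen to miss the mixed signal of control replicate 2. Of the 167 other genes called between ALA and SFA, 55.7% differed in the same direction between control replicate 2 and control replicate 1, with a median difference along that direction of 0.03 against a median size of 0.95 between the diets; with 1 control array of each kind, and a mixed pool among them, an effect of sex on those genes cannot be told apart from an effect of diet.

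Both diets differed from control in 6 lists, those of cell cycle, fetal-liver, macrophage, megakaryocyte, endothelial and stellate cell genes. ALA and SFA were at least as far apart as their mean was from control for 16.2% of the 111 members of these lists. If the sex of the pools were the source, control would lie between ALA and SFA. That share cannot decide this, since the lists were chosen for differing from the same control arrays on both diets, which favours a low share. Without control replicate 2 the 6 lists had medians of 0.46 to 1.69 on SFA. Both groups then have female signal, but control has 1 array. With an estimated correlation 0 lists were called in each comparison over all arrays. Control livers from more mature animals are a candidate explanation: of the genes not named elsewhere, 23 known to fall after birth (10 of them also in the fixed lists) had medians of 0.88 on ALA and 0.98 on SFA (1.19 and 1.36 over all 38), 42 known to rise after weaning had medians of -0.10 and -0.21 (-0.39 and -0.36 over all 53), and the largest of the 4 camera p-values was 0.0187. With an estimated correlation those p-values ran from 0.0266 to 0.255, and without control replicate 2 that of the rising list on SFA was 0.0642. Adult male-biased minus female-biased genes differed by 3.10 between control replicates 2 and 1 and by 0.089 between ALA and SFA, but with 1 control array of each kind and lists written after these values were seen, control livers past puberty cannot be told apart from another difference between those 2 pools, and the labels place all livers within 1 day of birth. A lower share of hepatocytes on both diets cannot be told apart from these. Its test used 70 markers with a mean log2 signal of at least 6, of erythroid, macrophage, megakaryocyte, endothelial, stellate and bile duct cells. The shifts differed between these cell types on SFA (permutation p = 0.00969) but not detectably on ALA (permutation p = 0.170). The bile duct markers had medians of -0.02 on ALA and -0.12 on SFA. Medians of the other types ran from 0.69 to 1.22 on ALA and from 0.73 to 1.80 on SFA. Granulocyte and lymphoid markers were not in that test. An effect of the diets themselves stays open and untested.

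The 2 arms of the clock moved apart between SFA and each of the other groups. The permutations below exchanged genes between the arms, not arrays between the groups. Their p-values measure the spread between genes and not between pools. Between ALA and SFA the 10 genes of the arm driven by E-box and D-box elements and the 4 of the opposite arm moved apart by 1.61 on the log2 scale (exact permutation p = 0.00599, adjusted over 4 comparisons 0.0160), and between SFA and control by -1.47 (exact permutation p = 0.00799), while between ALA and control the value was 0.14 (exact permutation p = 0.795). Livers collected at different times of day could give this, and the labels give no time of collection. An effect of sex cannot be told apart, since the arms differed by 0.21 between the control arrays, which is neither as large as it would need nor opposite, and by -0.66 between the mean of ALA and SFA and control (exact permutation p = 0.175), where sex would give 0 or more. SFA minus control replicate 1, both with female signal, gave -1.36 (exact permutation p = 0.0200), which goes against sex for that comparison but rests on 1 control array, and a shift of the clock by diet stays open and untested.

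Chance was examined by regrouping the arrays for the overall test of the 3 diets. Of the 15 ways to form 3 pairs, 1 gave at least the 1477 genes of the real groups, which is the real grouping itself, and the highest of the others gave 158. The groupings are too few for a share below 0.05.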

How the results depend on the processing

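The called lists and called named genes kept their direction under the alternatives run on them (the acute phase list in ALA versus control by camera, with a median of -0.01 without control replicate 1), but the numbers of called genes changed, and so did the balance between higher and lower genes: in ALA versus SFA 9 were higher and 27 lower without ALA replicate 2, and in SFA versus control 440 were higher and 295 lower without control replicate 1, 628 and 566 without the signal minimum, 625 and 607 with a replicate block, and 797 and 793 at an unadjusted p below 0.05 with a fold of at least 1.5. With the main values as 871 genes for ALA versus control, 1512 for SFA versus control, 168 for ALA versus SFA and 1477 for the overall test, leaving out each array in turn gave 267 to 475, 245 to 1428, 0 to 36 and 318 to 988 genes. The lone array left in a group is assumed there to vary like the other groups. Fewer arrays also leave fewer degrees of freedom, and the cause of the differences between arrays was not tested. The 13, 7 and 10 called lists became 10 to 15, 7 to 10 and 8 to 16 without single arrays, and the correlation of both diets' effects (r = 0.733) ran from 0.675 to 0.782 and was 0.694 without the signal minimum.

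Without moderation of the spread by limma, which leaves 3 degrees of freedom per gene, 2, 1 and 0 genes passed in the 3 contrasts (1976 at an unadjusted p below 0.05 in ALA versus SFA) and 1 in the overall test. At an adjusted p below 0.1 the numbers were 1631, 2572, 746 and 2856. ALA versus control gave 448 genes from only the 4 arrays compared, and 488 probes (72 of them with no listed gene) when all probes were tested. Over all probes, SFA versus control gave 752 higher and 1204 lower, so the balance moved further towards lower signal there. ALA versus SFA gave 32 genes without the signal minimum, 293 with a minimum of 6, 90 after quantile normalization, 421 with trend and robust moderation, 797 at an unadjusted p below 0.05 with a fold of at least 1.5, and 11 from only the 4 arrays compared, while all probes gave 397 probes, 211 of them with no listed gene. Apart from the numbers of samples, genes tested and the threshold, which these alternatives change by construction, the cause was not tested. With an estimated correlation camera called 0 lists in each contrast (2 at an unadjusted p below 0.05 in each). Fry called 8 lists in ALA versus control, 5 in SFA versus control and 6 in ALA versus SFA. Among them were 6 of the 13, 3 of the 7 and 4 of the 10 lists that camera called. The cell cycle list was not called by fry in any contrast (fry adjusted p = 0.122, 0.0587 and 0.347). Nor was cholesterol synthesis on ALA against control or against SFA (fry adjusted p = 0.250 and 0.347).

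A replicate block, which treats arrays with the same replicate number as processed together, left 719, 1232 and 0 genes in the 3 contrasts (2393 at an unadjusted p below 0.05 in ALA versus SFA), 1096 in the overall test and 28 of the 30 list calls. The differences between replicates 1 and 2 correlated across genes by -0.030 to 0.023 between the groups. These values show no pairing by replicate number, but they cannot exclude that such arrays were processed together. The block also costs a degree of freedom.

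Of 231 values of named genes, none of the called ones changed sign under any alternative run on them. Leaving out an array ended a call in 314 instances and made 25. Signs changed only for values near 0 or with a wide spread that had not passed. In ALA versus control Ppara was at 0.015 after 75th percentile centring and 0.043 after cyclic loess. Without single arrays it ran from -0.063 to 0.057, Cyp4a14 from -0.18 to 0.75, Igf1 from -0.059 to 0.20 and Cd36 from -1.87 to 0.0081, with the negative Cyp4a14 and the lowest Cd36 values both without control replicate 2. In SFA versus control Fads2 was at 0.026 and Igf1 at 0.011 after cyclic loess. Without single arrays Fads2 ran from -0.047 to 0.013, Cpt1a from -0.019 to 0.052, Cyp4a14 from -0.15 to 0.78, Pck1 from -0.14 to 0.16, Cd36 from -1.63 to 0.24 and Xist from -1.19 to 1.15. The highest Cyp4a14 and Xist values were both without control replicate 1, and the lowest Cd36 value was without control replicate 2. In ALA versus SFA Fasn ran from -0.90 to 0.080, Cyp4a14 from -0.065 to 0.014 and Igf1 from -0.039 to 0.22 without single arrays, with the sign changed without ALA replicate 1. What made them change was not tested.

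No rescaling moved the median of all genes by more than 0.1 on the log2 scale. Signal over background limits what these arrays can show for genes near the signal minimum, and 2 arrays per group limit every value.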

Other observations

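The lists of adult sex-biased genes in this part, and their tests, were chosen only after the data had been seen, while the other lists were fixed before.

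Several genes outside the called lists moved on both diets. The growth factor carrier gene Igfbp3 rose by 2.12 on ALA (SE 0.16) and by 2.15 on SFA (SE 0.16), the fatty acid carrier gene Fabp4, known from fat and endothelium, by 2.19 and 2.38 (SE 0.23 in each), and the growth regulator gene Myc by 1.26 and 1.60 (SE 0.15 in each). The sterol-regulated ubiquitin ligase gene Mylip rose by 1.17 and 0.82 (SE 0.16 in each) and the lipoprotein gene Apoa4 by 1.09 and 1.04 (SE 0.22 in each). In the fatty acid oxidation list, the pantetheinase gene Vnn1 was called at -1.45 on ALA and -1.25 on SFA (SE 0.27 in each), while the list was not called in either comparison (adjusted p = 0.251 and 0.633). The interferon response list was not called either (adjusted p = 0.0986 and 0.0759), and its members went both ways on both diets: Ifi27 was at -1.61 and -1.62 (SE 0.20 in each) and the antiviral gene Rsad2 rose by 1.37 and 1.40 (SE 0.22 in each).

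Genes known for higher expression in adult male liver were lower on both diets, and control replicate 2 carried much of this. Of 23 measured genes 0 rose and 7 fell on ALA (median -1.28, camera adjusted p = 9.78e-08, p = 0.194 with an estimated correlation), and 0 rose and 5 fell on SFA (median -1.17, camera adjusted p = 0.000146, p = 0.319 with an estimated correlation). Without control replicate 2 their median was -0.62 on ALA (camera adjusted p = 0.00343) and -0.37 on SFA (camera adjusted p = 0.0606, no longer called), and without control replicate 1 it was -2.30 and -2.29. Of 26 genes known for higher expression in adult female liver 4 rose and 1 fell on ALA (median 0.70, p = 0.374 with an estimated correlation), and 6 rose and 1 fell on SFA (median 0.58, p = 0.337 with an estimated correlation). Without control replicate 2 the median of these was 0.08 and -0.02, and without control replicate 1 it was 1.05 and 1.10. Between the control arrays, replicate 2 minus replicate 1, the medians were 1.79 for the male-biased and -1.18 for the female-biased genes. The steroid dehydrogenase gene Hsd3b5, chosen after its values were seen, had a log2 signal of 10.8 on control replicate 2 and of 4.13 to 4.87 on the other 5 arrays.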
